A study of Mus musculus with 12 samples.

How the data were processed

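TET2 chromatin immunoprecipitation sequencing (ChIP-seq) was performed in cultured mouse hematopoietic cells of 2 types. ChIP-seq recovers the DNA fragments bound by a protein with an antibody and locates them in the genome. The first cell type was a culture of hematopoietic cells immortalized by a retroviral AML1-ETO transgene, called myeloid cells here. The second was a culture of acute myeloid leukemia cells that carried Npm1 and Flt3 mutations, called AML cells here. Of the 12 libraries, 8 were made with an antibody against the N-terminal part of TET2, from 2 wild-type and 2 Tet2-knockout samples of each cell type. The other 4 were 1 input and 1 IgG library per cell type. Per the labels' protocols, cells grew in 50 ng/ml stem cell factor, 10 ng/ml interleukin 3 and 10 ng/ml interleukin 6. They were crosslinked with 2 mM disuccinimidyl glutarate followed by 1% formaldehyde, and chromatin was sheared to fragments of 200 to 500 bp. Double crosslinking of this kind also captures proteins that touch DNA through partners.

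Per the submitters' processing notes, Trimmomatic, Bowtie2 and MACS2 were used with the mm10 build; versions, thresholds and options are not given in the sources used here. The authors deposited 1 list of TET2 binding sites per cell type, and per the file headers each row holds a chromosome, a start and an end. The lists have no score, height, fold or p-value per site and no value per library. Whether a list came from pooled or separate replicates, and how knockout, IgG and input libraries entered it, is not given in the sources used here. Because no read counts were among the files used, the depth behind each site is unknown. No site carries a replicate error. Intervals below cover counting error over sites only, and a difference between lists has no replicate check. Whether starts are counted from 0 or 1 is also not stated, which leaves positions uncertain by 1 bp. Neighbouring deposited sites overlapped by up to 492 bp in the AML list and 496 bp in the myeloid list. This happened 106 and 884 times, so sites of a list that overlapped by at least 1 bp were merged into 1 site. In the AML list 1 site on an unplaced contig was left out, and chromosomes 1 to 19, X and Y were kept.

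Genes were taken from an NCBI RefSeq gene table of the GRCm38.p6 assembly, which has the chromosome coordinates of mm10. It holds 21883 protein-coding genes on the chromosomes used, with start and end but no strand, exons or sequence. The planned distances to transcription start sites were therefore replaced by distances from the site midpoint to the nearer end of a gene, at either side. A gene end here can be the start or the end of transcription. The planned scans of motifs, GC and CpG content and the planned comparisons of site strength and of wild-type with knockout signal could not be made from these files. Each site was assigned to the gene with the nearest end within 100 kb. A gene's territory was the sequence nearer to its ends than to those of any other gene, within 100 kb. The expected number of sites of a gene was its share of all territory multiplied by the number of assigned sites.

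The overlap of the lists was compared with 1000 sets of AML sites placed at random on their own chromosome, from 3 Mb to the last annotated base or site (one-sided). Location shares were compared by Fisher's exact test (two-sided) with each other and with 10 random windows per site, with Benjamini-Hochberg adjustment over 15 tests. Shares have exact Clopper-Pearson 95% intervals. Sites lie in clusters and are not independent, so the main share difference was also resampled over 1 Mb blocks 1000 times. Gene lists were written down before the data were examined, 13 by name and 2 by symbol (ribosomal: Rpl or Rps and a digit; olfactory: Olfr). All 249 named entries matched the table. Some genes, such as Runx1, Kit and Tet2, are in more than 1 list, so the results of the lists are not independent. For each list, the number of genes with at least 1 site was compared with 10000 random gene lists matched on 10 classes of territory size. This permutation test was two-sided, with Benjamini-Hochberg adjustment over 30 tests, and the smallest adjusted p it gave was 0.00060. The difference between cell types was tested per list and, as a test added after the data were seen, per gene with at least 5 unshared sites. Both used Fisher's exact test on AML-only against myeloid-only sites.

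The genes named in the text were set by a rule before the data were examined. It took the 10 genes with most sites per list and in both together, with ties at the limit broken by symbol, up to 4 members of each gene list with most sites and up to 2 with sites in 1 cell type alone, Tet2, and the 5 widest sites per list. Its part on the highest-scoring sites could not be applied. Some genes that the rule takes are not reported here. Alternatives changed the overlap criterion, the random placement, the distance that defines a gene end, the assignment limit, the gene set and the matching. On simulated lists with no relation, the overlap was called in 1 of 10 simulations at 0.05, and 0 of 300 gene list tests were called. Those sites were placed at random, without the clustering and gene-end excess of the real sites. The simulations therefore do not show how often the tests err on lists like these. With 500 shared sites planted, the mean excess overlap recovered was 494.3, and 30 of 30 planted gene list tests were recovered when 60% of a list's genes were given a site (10 simulations per setting, 21883 genes). Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.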

Results

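The study compared TET2 occupancy in blood-forming cells that had or lacked full-length TET2, an enzyme that oxidizes 5-methylcytosine in DNA. Its title places the question at enhancers and the recruitment of transcription factors. The deposited list of AML cells held 7002 TET2 sites and that of myeloid cells 19706. Sites had a median width of 720 bp (quartiles 686 and 768 bp) in the AML list and 706 bp (664 and 767 bp) in the myeloid list. After merging, 6895 AML sites covered 5.13 Mb and 18822 myeloid sites covered 14.1 Mb. The myeloid list was 2.73 times as long as the AML list. The 12 libraries comprised 2 wild-type and 2 knockout TET2 libraries, 1 input and 1 IgG per cell type, and the lists hold no value for any single library. Tet2 itself (chromosome 3, 133463677 to 133545136) had 1 AML site, which was shared, and 7 myeloid sites, of which 2 lay within 1 kb of a gene end.

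Most TET2 sites of the AML list were also in the longer myeloid list. Of the 6895 AML sites, 4922 shared at least 1 bp with a myeloid site (71.4%, 95% interval 70.3 to 72.4). These were 26.2% of the myeloid sites (25.5 to 26.8), so 1973 sites were AML-only and 13900 were myeloid-only. Of the 21883 protein-coding genes, 4074 had an AML site and 8756 a myeloid site, and 89.1% of the former were among the latter. This share follows in part from the shared sites and was not tested on its own. Randomly placed AML sites met a myeloid site 80.1 times on average (SD 8.93 over 1000 placements, highest 110). The observed number was 61.4-fold higher (one-sided permutation p = 0.000999, the smallest these placements can give). With myeloid sites drawn at random to the length of the AML list, 1803 AML sites on average were shared (26.2%). Such draws lose shared sites in proportion, so this value repeats the shared part of the myeloid list and does not test the overlap. The observed number was 20.8-fold higher than random when each AML site was instead moved by 5 to 50 kb.

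All AML sites around Runx1 were shared with the myeloid cells, as were 71.4% of all AML sites. Runx1, a transcription factor required for blood stem cell formation and the gene whose product is the AML1 part of AML1-ETO, lies on chromosome 16 from 92601466 to 92826074. It had 8 AML sites (exact Poisson 95% interval 3.45 to 15.8; 1.19 expected from its territory), and all 8 were shared. It had 14 myeloid sites (7.65 to 23.5; 3.34 expected), more than any other gene in that list.

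**Figure D1:**
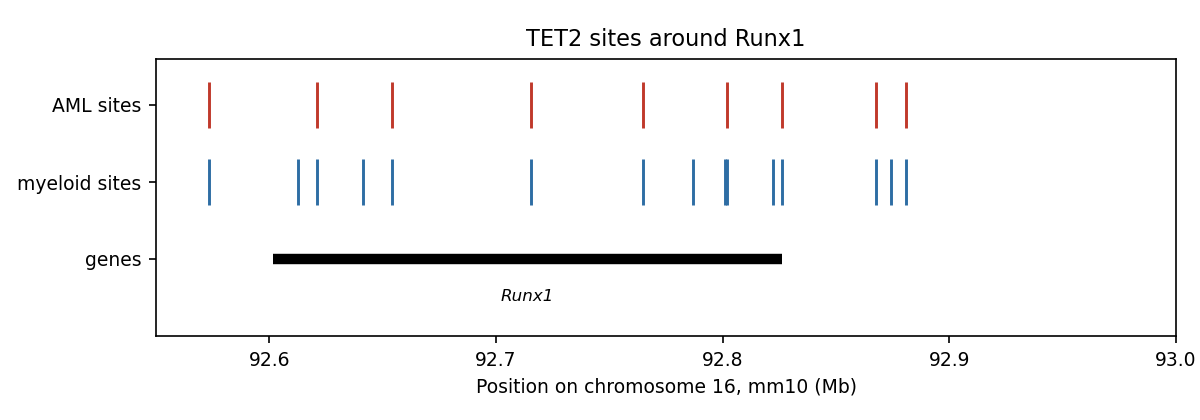
Sites of the AML list (top) and the myeloid list (middle) as vertical lines, and protein-coding genes (bottom), by position on chromosome 16 in Mb of mm10. All 9 AML sites in the window coincide with a myeloid site, and the myeloid list has 15 sites there.

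Among location classes, the ends of genes differed most between AML-only and myeloid-only sites by odds ratio. In the AML list 8.82% of sites (8.16 to 9.51) lay within 1 kb of an end of a protein-coding gene, against 22.6% (22.0 to 23.2) in the myeloid list. Among sites found in 1 cell type alone the gap was wider, at 5.37% of the AML-only sites (4.42 to 6.46) and 26.9% of the myeloid-only sites (26.2 to 27.7). The odds of lying at a gene end were 6.50 times as high for myeloid-only as for AML-only sites (5.32 to 8.01; Fisher's exact test, adjusted p = 5.80e-124). The difference was 21.6 percentage points, with an interval of 20.2 to 23.0 from resampling 1 Mb blocks. Shared sites lay between these values, at 10.2%. Some 600 genes had an AML site at an end and 4059 genes a myeloid site at an end.

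Away from gene ends, the lists resembled each other more. Gene bodies held 45.2% of AML sites (44.0 to 46.3) and 41.8% of myeloid sites (41.1 to 42.5), against 39.4% and 39.3% of random windows. Intergenic sites made up 46.0% of the AML list (44.8 to 47.2) and 35.6% of the myeloid list (34.9 to 36.3), against 57.4% and 57.5% of random windows. The median distance to a gene end was 16.9 kb (quartiles 5.08 and 47.0 kb) in the AML list and 9.72 kb (1.38 and 33.6 kb) in the myeloid list. It was 46.8 and 46.0 kb for the random windows of these lists. Sites over 10 kb from any gene end were 61.9% of the AML list (60.7 to 63.0) and 49.5% of the myeloid list (48.7 to 50.2). Both lists held more gene-end sites than random windows, with an odds ratio of 2.93 (2.66 to 3.22) in the AML list and 8.85 (8.48 to 9.24) in the myeloid list. With all annotated genes in place of protein-coding genes, the shares over 10 kb were 42.5% and 33.8%. The odds ratio of AML-only over myeloid-only sites at gene ends was 0.154, against 0.255 with all annotated genes and 0.107 with a limit of 0.5 kb.

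**Figure D2:**
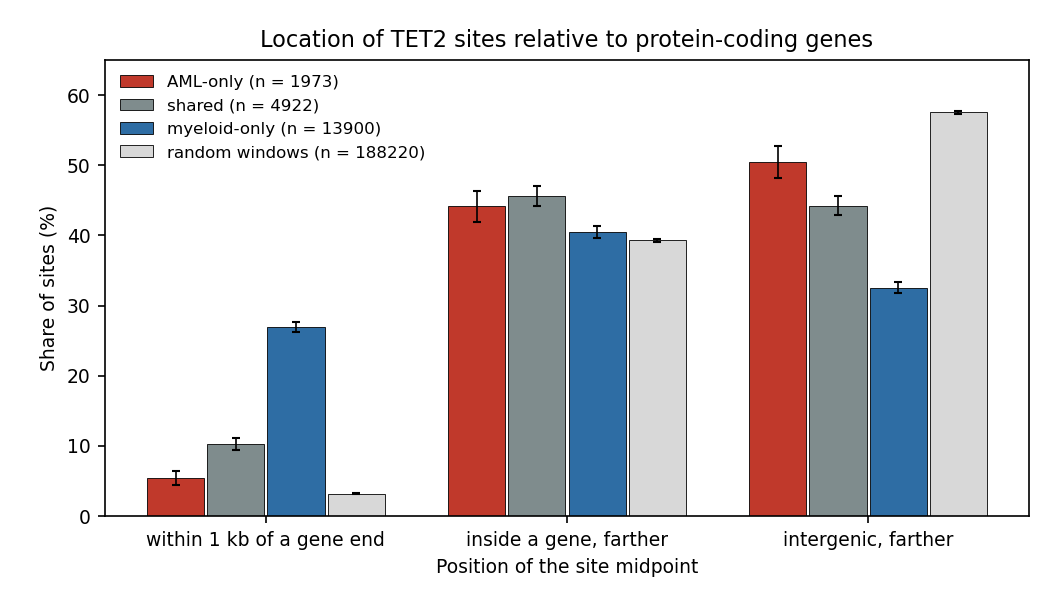
Share of sites in percent (bars, with exact 95% binomial intervals) by position relative to protein-coding genes, for AML-only, shared and myeloid-only sites and random windows. Gene ends hold 26.9% of the myeloid-only sites and 5.37% of the AML-only sites.

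Granulocyte genes carried TET2 sites in both cell types. Of 20 genes of granule and neutrophil products, 17 had an AML site (2.52 expected from genes of matched territory) and 19 a myeloid site (6.92 expected). Both passed the permutation test, each at an adjusted p of 0.00060. S100a8, which encodes a subunit of the neutrophil protein calprotectin, had 2 AML sites and 3 myeloid sites, with 1 of each at a gene end. Itgam, the integrin chain CD11b, had 2 and 3. Ltf, which encodes lactoferrin, had 2 and 3, and the neutrophil antigen gene Cd177 had 3 and 2. Csf3r, the receptor of granulocyte colony-stimulating factor, had 0 AML sites and 1 myeloid site, and Cybb, a subunit of the phagocyte oxidase, had 0 and 2. Their territories gave 0.44 and 0.49 AML sites expected. Elane, named after its values were seen, was the 1 member with no site in either list. Its small territory gave only 0.017 AML sites and 0.048 myeloid sites expected.

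Genes of myeloid transcription factors also had a site more often than matched genes in both cell types. All 27 of the list had a myeloid site (12.2 expected) and 19 an AML site (6.43 expected), at an adjusted p of 0.00060 in each list by the permutation test. Cebpb, a factor of granulocyte and macrophage differentiation, had 5 AML sites and 11 myeloid sites, where 0.41 and 1.16 were expected. Runx3 had 6 and 7, and Ikzf1, which encodes Ikaros, had 4 and 7. Ikzf2 (9 myeloid sites) and Stat3 (3 myeloid sites) had 0 AML sites, where 1.17 and 0.22 were expected from their territories.

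Genes that transmit the signals of the cytokines in the medium formed the third group. Of 25 genes of stem cell factor, interleukin 3 and interleukin 6 signalling, 17 had an AML site (5.23 expected) and 23 a myeloid site (10.6 expected; permutation test, adjusted p = 0.00060 in each list). Mcl1, an inhibitor of apoptosis, Dusp6, a phosphatase of ERK kinases, the kinase gene Pim1 and the adaptor gene Gab2 each had 2 AML sites and 5 myeloid sites. In each of these 4 genes the AML sites were shared. Socs1, a feedback inhibitor of JAK kinases, had 6 myeloid sites, 3 of them at a gene end, and 0 AML sites. Csf2rb, the common beta chain of the interleukin 3 receptor, had 4 myeloid sites and 0 AML sites. Only 0.080 AML sites at Socs1 and 0.18 at Csf2rb were expected from their territories, so these counts of 0 say little. With gene-end sites alone the cytokine list did not pass in the AML list (adjusted permutation p = 0.563). That was the highest adjusted p over the alternatives. The lowest, 2.77e-08, came from an exact binomial test on sites per territory, which counts neighbouring sites as independent.

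Monocyte and progenitor genes also had more occupied members than matched genes. Of 16 monocyte and macrophage genes, 12 had an AML site (3.03 expected; permutation test, adjusted p = 0.00060) and 14 a myeloid site (6.53 expected; adjusted p = 0.0015). The fractalkine receptor gene Cx3cr1 had 3 AML sites and 4 myeloid sites. The chemokine receptor gene Ccr2 had 1 and 3, and the Toll-like receptor genes Tlr2 and Tlr4 had 1 and 5, and 2 and 2. Cd68 and Cd74 had 1 myeloid site each and 0 AML sites (0.011 and 0.079 expected from their territories). With gene-end sites alone the monocyte list did not pass in either cell type (adjusted permutation p = 0.306 and 0.305). Over the alternatives, an exact binomial test included, the lowest adjusted p were 2.98e-05 and 1.05e-05. The monocyte list passed in 13 of 20 draws of the myeloid list at the size of the AML list. Of 22 progenitor and leukemia genes, 11 had an AML site (4.86 expected; adjusted p = 0.0096) and 15 a myeloid site (9.15 expected; adjusted permutation p = 0.0296). Erg and Etv6, both ETS factors, had 1 and 2 AML sites and 8 myeloid sites each, Gata2 had 2 and 7, and Cd34 had 2 and 5. Myb (4 myeloid sites) and Tal1 (3 myeloid sites) had 0 AML sites, where 0.45 and 0.11 were expected from their territories. Hoxa5, Hoxa7, Hoxa9 and Hoxa10, named after their values were seen, had 0 sites in either list. Their territories are small, with at most 0.044 AML sites and 0.12 myeloid sites expected per gene, so these counts of 0 say little. The progenitor list did not pass in either cell type by the permutation test when sites had to lie within 20 kb of a gene end (adjusted p = 0.296 and 0.163). Over all its alternatives, an exact binomial test included, the adjusted p ran from 0.00415 to 1 in the AML list. In the myeloid list it ran from 1.82e-06, by the binomial test, to 0.163.

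Of 14 mast cell, basophil and eosinophil genes, 7 had an AML site (1.93 expected; permutation test, adjusted p = 0.00429). In the myeloid list 9 had a site, which did not pass (5.05 expected; adjusted permutation p = 0.101). With all annotated genes it did (adjusted permutation p = 0.00675; from 1.77e-10 to 1 over its alternatives, an exact binomial test included). Srgn, which encodes the granule proteoglycan serglycin, had 1 AML site and 7 myeloid sites, Il1rl1 had 2 and 5, Siglecf 2 and 4, and Hdc 2 and 3. With gene-end sites alone 1 of these genes had an AML site (adjusted permutation p = 1). Over the alternatives the lowest adjusted p in the AML list, 2.34e-05, came from the exact binomial test. The proteases Cma1 and Mcpt4 had 1 myeloid site each.

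Lists of genes of other blood lineages did not pass the permutation test in either cell type. Of 17 erythroid and megakaryocyte genes, 2 had an AML site and 5 a myeloid site (2.55 and 6.17 expected). Zfpm1 had 5 myeloid sites, and Tfrc and Vwf had 1 site in each list. Of 13 B cell genes, 1 and 2 had a site (2.02 and 4.80 expected), with 1 in each list at Igll1 and 2 myeloid sites at Cd22. Of 15 T and NK cell genes, 3 and 7 had a site (3.10 and 6.31 expected). Cd3d and Ncr1 had 1 site in each list, Gata3 had 2 myeloid sites and Cd2 had 1 AML site. None of these 6 results passed (permutation test, adjusted p from 0.268 to 1). The B cell list passed as lower in the myeloid list by an exact binomial test on sites per territory, with 3 sites where 9.62 were expected (adjusted p = 0.0475; up to 0.841 over the alternatives).

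Olfactory receptor genes had few TET2 sites in both lists. Of 1110 olfactory receptor genes, 18 had an AML site (127 expected) and 39 a myeloid site (370 expected; permutation test, adjusted p = 0.00060 in each list). Olfr372 and Olfr164 had 2 AML sites and 1 myeloid site each, Olfr1423 had 1 and 2, Olfr1258 had 0 and 3, and Olfr402 had 0 and 2. Olfactory genes lie in clusters and are not independent. Of 20 neuronal genes, 3 had a site in each list, fewer than matched genes in the myeloid list (9.28 expected; adjusted permutation p = 0.0109). The same comparison did not pass in the AML list (5.60 expected; adjusted permutation p = 0.408), but an exact binomial test on sites per territory did, with 3 AML sites where 15.3 were expected (adjusted p = 0.000481; up to 1 over the alternatives). The neuronal result of the myeloid list did not pass with all annotated genes (adjusted permutation p = 0.731), and passed in 3 of 20 draws at the size of the AML list. Over its alternatives, an exact binomial test included, the adjusted p ran from 1.76e-12 to 0.731. Gria2 and Neurod1 had 1 AML site and 0 myeloid sites each. Of 16 liver genes, 1 and 4 had a site (3.01 and 6.61 expected; adjusted permutation p = 0.440 and 0.408). The exact binomial test gave 4 myeloid sites at these genes where 10.7 were expected, which passed as lower (adjusted p = 0.0475; up to 1 over the alternatives). G6pc had 1 AML site, and Ahsg, Apob and Cyp7a1 had 1 myeloid site each.

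Genes of DNA methylation, genes mutated in human AML and ribosomal genes exceeded matched genes in the myeloid list and did not pass in the AML list. The differences between cell types for these lists, tested on unshared sites, did not pass. The DNA methylation and AML mutation lists have Tet2, Dnmt3a, Idh1 and Idh2 in common. In 20 draws of the myeloid list at the size of the AML list, the DNA methylation list exceeded matched genes in 6, the AML mutation list in 15 and the ribosomal list in 2. Of 19 genes of DNA methylation and its removal, 16 had a myeloid site (8.27 expected; permutation test, adjusted p = 0.00185) and 3 an AML site (4.13 expected; adjusted p = 0.847). Besides Tet2, Dnmt1, the maintenance methyltransferase, had 1 AML site and 2 myeloid sites. Cxxc5 and Gadd45b had 4 and 3 myeloid sites and 0 AML sites (0.34 and 0.058 expected from their territories). Of 25 genes mutated in human AML, 21 had a myeloid site (11.3 expected; adjusted permutation p = 0.0015) and 8 an AML site (6.04 expected; adjusted p = 0.629). An exact binomial test on sites per territory gave 19 AML sites at these 25 genes where 10.7 were expected (adjusted p = 0.0307; from 0.0307 to 1 over the alternatives). Of these 19 sites, 8 lay at Runx1 alone (1.19 expected), and the binomial test counts neighbouring sites as independent. Ptpn11 had 1 AML site and 7 myeloid sites, and Cbl had 2 and 3. Cebpa and Bcor had 2 myeloid sites each and 0 AML sites (0.24 and 1.16 expected from their territories). Of 97 genes under the ribosomal symbol rule, 49 had a myeloid site (32.2 expected; adjusted permutation p = 0.00060) and 10 an AML site (12.02 expected; adjusted p = 0.803). The rule also takes in kinases such as Rps6ka1 (3 AML sites, 11 myeloid sites) and Rps6ka5 (2 and 3). Rpl5 had 2 sites in each list, and Rps10 had 1 and 2. Rpl13 and Rpl24 had 2 myeloid sites each and 0 AML sites (0.040 and 0.088 expected from their territories). The ribosomal result did not pass against unmatched lists (adjusted permutation p = 0.0790). Over its alternatives, an exact binomial test included, the adjusted p ran from 0.000271 to 0.968. With sites over 1 kb from gene ends, 20 ribosomal genes had a myeloid site where 19.3 were expected (adjusted permutation p = 0.968).

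**Figure D3:**
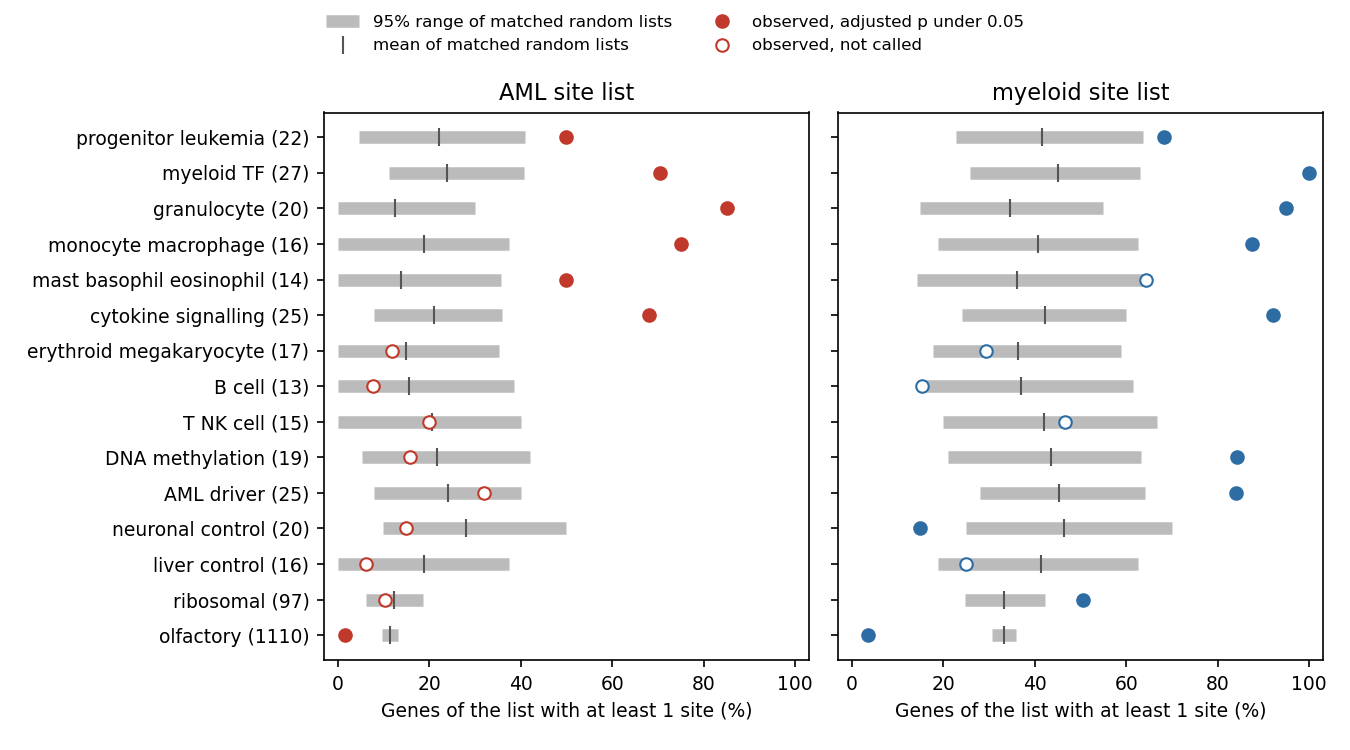
Percent of the genes of each list with at least 1 TET2 site in the AML list (left) and the myeloid list (right). Points are observed values (filled where the adjusted p is under 0.05), ticks and gray bars the mean and 95% range of 10000 matched random lists, and numbers in parentheses the genes per list. The granulocyte list reaches 85% and 95%, and the olfactory list 1.62% and 3.51%.

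The difference between the cell types was then tested directly, on unshared sites. Among 1666 AML-only and 12721 myeloid-only sites assigned to a gene, 0 of the 15 lists differed after adjustment (Fisher's exact test), and 1 did at an unadjusted p under 0.05. That list was DNA methylation, with 0 AML-only and 32 myeloid-only sites (odds ratio up to 0.932 at 95%; unadjusted Fisher exact p = 0.0457, adjusted p = 0.613). The intervals were wide. For granulocyte genes the odds ratio of AML-only over myeloid-only sites was 1.04 (0.199 to 3.47), and for cytokine signalling genes 0.669 (0.209 to 1.66). No difference between cell types was therefore detectable for these lists at this number of sites. Of the 344 genes with at least 5 unshared sites, 3 differed (Fisher's exact test with Benjamini-Hochberg adjustment, a test added after the data were seen). They were Gm52481 on chromosome Y (11 AML-only sites and 1 myeloid-only site, adjusted Fisher exact p = 1.80e-07), Mid1 on chromosome X (9 and 0, adjusted p = 6.32e-07) and Adtrp on chromosome 13 (7 and 0, adjusted p = 3.17e-05). Within 20 kb of a gene end Mid1 alone was called, as Gm52481 and Adtrp then had 4 and 2 unshared sites, too few to be tested, and with no limit of distance 6 genes were called, these 3 included. The test counts neighbouring sites as independent, and the 9 Mid1 sites formed 1 group of 39.4 kb. The p-values of the 3 genes may therefore overstate the evidence. Only an excess of AML-only sites could be detected for a single gene. The tested genes had at most 13 unshared sites, and 13 myeloid-only sites with 0 AML-only sites would give a two-sided Fisher exact p of 0.386. In the fixed lists 19 entries had enough unshared sites, from 8 of the 15 lists, and the granulocyte and monocyte lists had 0. Of these 19 entries 0 differed, adjusted over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05.

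Runx1, Atp8b4 and Susd1 were high in both lists by number of sites, without regard to territory size. Besides Runx1, the genes with most sites summed over both lists were Atp8b4 (8 AML sites, 11 myeloid sites), Susd1 (8 and 11), Gcnt2 (6 and 12), Tle3 (8 and 9), F13a1 (7 and 10), Map4k4 (7 and 10), Ptpre (4 and 13), Rbms1 (5 and 12) and Rin3 (5 and 12). Other genes high in the AML list, where several tied at 7 sites, were Gm52481 (11 AML sites, 1 myeloid site), Mid1 (9 and 0), Igf1r, the receptor of insulin-like growth factor 1 (8 and 8), Adtrp (7 and 0) and Klf13 (7 and 7). Other genes high in the myeloid list, where several tied at 11 sites, were Zfp217 (3 and 12), Zfp608 (4 and 12), Cebpb and Cmip (3 and 11). The widest deposited sites were 1468 bp at Eif3b in the AML list and 2618 bp at Mdga1 in the myeloid list. The genes with the nearest ends to the next widest sites were Dyrk1a, Sstr2 (75.1 kb away), Snap47 (14.7 kb away) and Gm52481 in the AML list, and Gm20783, Vps26c, Crlf2 and Wdfy2 in the myeloid list.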

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

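The tests of single genes, by site width, of ribosomal genes and of the surroundings of the loci were chosen after the results were seen. Gene ends drew attention because AML-only and myeloid-only sites differed there, with an odds ratio of 0.154 for AML-only over myeloid-only sites. A myeloid list placed in gene-rich regions is a technical candidate explanation. After each site was moved by 5 to 50 kb, the difference of gene-end shares was 2.02 percentage points (0.770 to 3.49 over 100 moves), against 21.6 observed, which argues against it as the whole cause. An AML list that kept only sites wide in the myeloid list would share gene-end and other myeloid sites equally at equal width. The odds ratio of being shared, gene-end against other myeloid sites, was 0.217 over width classes (0.194 to 0.243). Wider myeloid sites were shared more often (8.12% in the narrowest class, 43.7% in the widest), but at equal width gene-end sites were still shared less. These widths were those of the myeloid list, so a stricter cut by width or strength within the AML list stays open. Signal at the ends of active genes that does not need TET2 stays open: 33 of 97 ribosomal genes had a myeloid gene-end site (11 to 26 in matched random lists), and without knockout values this cannot be told apart from TET2 binding. A difference in depth, which the lists do not record, and a difference between the cell types themselves may also contribute and were not tested.

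The genes Gm52481 (11 AML-only sites), Mid1 (9) and Adtrp (7) drew attention because their unshared sites differed between the lists. Mid1 spans the boundary of the region that X and Y share, so copies of 1 sequence placed on both chromosomes are a candidate explanation for the first 2 genes. The best single offset paired 4 of 9 X sites with Y sites, within the range of random placements (95th percentile 6, permutation p = 0.815), and without the sequence this stays open. A gain of signal that made most unshared sites in the 1 Mb around Adtrp AML-only is argued against. There, 4 of 36 unshared sites were AML-only (11.1%, 3.11 to 26.1), against 12.4% of all unshared sites. A smaller gain spread over this region stays open, as the interval reaches above 12.4%. A gain around Mid1 and Gm52481 also stays open, as only 4 unshared sites lay around Mid1, of which 0 were AML-only, and 0 around Gm52481. So does a real difference between the AML and myeloid cultures, which have 1 list each.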

How the results depend on the processing

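Trimmed sites, assignment to the host gene, sites split by gene ends, draws of the myeloid list at the AML size for gene lists, and the test of single genes with its alternatives were chosen after the data were seen. The overlap exceeded random placement under 6 alternatives (20.8-fold to 185.0-fold); draws of equal list size scale the observed and random overlap alike and so do not test it. The gene-end odds ratio of AML-only over myeloid-only sites ranged from 0.107 to 0.255 over other definitions and from 0.148 to 0.160 without 1 chromosome. With all annotated genes, the share of sites over 10 kb from a gene end was 42.5% instead of 61.9% in the AML list and 33.8% instead of 49.5% in the myeloid list, since that table has more gene ends. The number of AML gene lists above matched genes was 2 instead of 6 with gene-end sites alone (granulocyte and transcription factor genes), and of those below 2 instead of 1 with the binomial test on sites per territory. The number of myeloid lists below matched genes was 2, against 1 with all annotated genes, with unmatched lists, with assignment to the host gene, with gene-end sites alone and with draws at the AML size, and 4 with the binomial test. Genes that differed between the lists numbered 3, against 1 within 20 kb (62 genes tested) and 6 with no limit of distance (477 tested).

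Some lists that never passed changed sides of their expected number, all without passing. The number of T and NK cell genes with an AML site was 3 against unmatched lists and 1 with gene-end sites. With a myeloid site it was 5 within 20 kb and 1 with gene-end sites, and the binomial test counted 8 sites. Ribosomal genes with an AML site numbered 9 within 20 kb, 7 with all annotated genes and 3 with gene-end sites, and the binomial test counted 15 sites. Erythroid and megakaryocyte genes with a myeloid site numbered 4 with all annotated genes and 3 with gene-end sites. Unless stated, the cause was not tested. Stricter score thresholds, motif, GC and CpG content, site strength and the knockout comparison were not run, because the lists hold no score or knockout value and no sequence was used. No paired analysis was possible because each cell type has 1 list with no value per replicate. Depth is unknown, so the lengths of the lists cannot be compared as numbers of bound sites.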

Other observations

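The grouping of sites and both tests on chromosome X were chosen after the data were seen. When sites were joined at the stitching distance customary for super-enhancers, 10 AML groups held at least 5 sites (58 sites, 0.841% of the list), and 100 random placements gave 0 on average. The myeloid list had 216 such groups (1251 sites, 6.65%), against 2.18 on average and 7 at most in random placements. A longer list forms more such groups, and the counts of the lists were not compared at equal length. Besides Mid1 (9 sites), AML groups lay at Il17ra, a receptor chain of interleukin 17 (7 sites), Thbs1, which encodes thrombospondin 1 (6 sites), C5ar1, the receptor of complement C5a (6 sites), and S100a8 with its neighbour S100a9 (5 sites). Further groups of 5 lay at Ccnd3, which encodes cyclin D3, at Cd300lb and Cd300a, and at 1600014C10Rik. The largest myeloid groups were at Thbs1 (12 sites, chromosome 2, 117951279 to 118013704), at Mapkapk3 and Cish (12 sites), at Plek, which encodes pleckstrin (11 sites), at the chemokine genes Ccl6, Ccl3 and Ccl4 (11 sites) and at Tpst2, Cryba4 and Crybb1 (11 sites). Groups of 10 sites lay at Itgb2, the beta chain of leukocyte integrins, at Sh2b2 and at Gm46963. The list of largest groups was made after their sizes were seen.

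Chromosome X had fewer sites per Mb than any autosome in both lists, at 0.626 in the AML list (autosomes 2.12 to 4.29) and 1.71 in the myeloid list (autosomes 5.75 to 12.05). The ratio of X to the autosomes was 0.222 in each list. A lower gene density of X is a candidate explanation, but per protein-coding gene the AML ratio was still 0.331, and X lay below every autosome in both lists (0.109 against at least 0.206 in the AML list, 0.297 against at least 0.608 in the myeloid list). A single copy of X per cell may lower the signal and the number of sites passing a threshold, for which the ratio of 0.222 decides nothing without read depth. No biological explanation was tested.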
